A study of Macaca fascicularis with 605 samples.

How the data were processed

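Transcript levels were measured by SC3-seq, a method that sequences tags from the 3-prime ends of amplified single-cell cDNA, in 605 single cells of cynomolgus monkey. The cells comprised 540 cells of embryos, 28 embryonic stem cells (ESCs), 12 primordial germ cell-like cells (PGCLCs) induced from ESCs and 25 gonadal germ cells. Per the labels, the cells formed 20 groups by embryonic day, cell line or culture condition. CMK6 and CMK9 ESCs were kept in a conventional ESC medium on mouse feeder cells, and 656BTAG ESCs, a line with the BTAG reporter, in a medium with bFGF and the inhibitor IWR1. PGCLCs were BTAG-positive cells sorted on day 8 of induction in aggregates with Y27632 (10 µM), EGF (50 ng/ml), BMP4 (200 ng/ml), LIF (1000 U/ml) and SCF (100 ng/ml). The basal medium was GMEM with serum replacement (GK15) or Advanced RPMI with B27 (aRB27). The reporter genes behind the name BTAG were not given in the sources used here. Per the labels, gonadal cDNAs had been assigned to germ cells by quantitative PCR before sequencing.

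The deposited table held RPM (reads scaled by the authors to the mapped reads of each cell) for 26018 genes, with 1 column per cell. Per the submitters' processing notes, cutadapt 1.3, TopHat 1.4.1 and Cufflinks 2.2.0 were used upstream. The genome build was not given in the sources used here, so no positions of genes are given. All columns were mapped to samples by their titles. The RPM of a cell summed to between 988458 and 996773. In 549 columns the values were multiples of the value of 1 read, and 99.24% of their values above 0 were whole within 0.1 read. A read depth, 151085 to 9774647 reads with a median of 1977780, was taken from the value of 1 read in 603 cells, including cells outside those columns. In these at least 95% of the low values were whole. The median number of genes above 0 RPM per cell was 9691 (5682 to 14264). Reads carried no molecular identifiers in the sources used here, so limits from read counts cover counting error only. Of the gene IDs, 20272 were also in the RefSeq gene table, and 673 genes named LOC took their RefSeq symbol from it. A further 8622 genes kept a LOC name and are counted but not named. T is the gene symbol of the table for TBXT.

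Cells were not treated as replicates. The labels name no animal or culture for a cell, so the cells of a cell line, a culture condition or an embryonic day were averaged into a unit. Units with at least 5 cells were used. The p-values therefore measure only the spread between these units, which are different lines, media or days rather than repeats of a condition. Genes with a unit mean of at least 10 RPM in at least 2 units were tested on log2(mean RPM + 1) with limma 3.58.1 (R 4.3.3, eBayes with trend). A gene near 0 in the other classes enters only through the class where it is high. This filter therefore favours counts of list members in that direction. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. The first fit held 3 ESC units, 2 PGCLC units and 4 gonadal units. The second held EPI-like cells of 3 days before and 4 days after implantation with the 3 ESC units. The third added PGC-like cells of E13 and E16 to the first. All classes of a fit shared 1 estimate of the spread. The comparisons within the 656BTAG line had 1 culture per group and no test. They are given as log2 ratios of (mean RPM + 1) with the SD over cells, and their counts at a log2 ratio of 2 are counts by size, not calls. The labels gave no cell types for embryo cells. Types were rebuilt by Leiden clustering (scanpy 1.11.5, leidenalg 0.10.2) of the 540 embryo cells on the 1500 most variable genes, with 20 principal components, 10 neighbours and a resolution of 1. A cluster took a name with the ending "-like" when its marker score was at least 2, exceeded the next type by at least 1 and rested on at least 3 detected markers. These names are not the authors' annotation. The genes that define a type are not independent evidence about that type. Intervals on shares of cells are exact 95% Clopper-Pearson intervals.

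A set of 21 gene lists was tested with camera of limma, with a preset correlation of 0.01 between genes and again with an estimated correlation. They were core, pre-implantation and post-implantation pluripotency, early and late germ cell, meiosis, mesoderm and primitive streak, BMP response, DNA and histone modifiers, proliferation, endoderm, trophectoderm, amnion, extraembryonic mesenchyme, gonadal somatic cell, endothelium and blood, neural ectoderm, stress and dissociation, cholesterol synthesis, glycolysis and oxidative phosphorylation. In the untested comparisons, the median log2 ratio of a list is given with its percentile among 10000 random lists of the same size matched on mean expression. Named genes followed a rule. In tested comparisons they were the 10 genes in each direction with the largest change among those called, with units that did not overlap and at least 50 RPM in the higher class. In day 8 against day 0 they were the 10 in each direction with the largest ratio in the medium with the smaller ratio. Between media they were the 10 in each direction that were above 0 in at least 5 cells of the higher group. Members of the lists could be named as examples, and 10 genes (PRDM1, TFAP2C, SOX17, NANOS3, KIT, POU5F1, NANOG, SOX2, DAZL and DDX4) were given in every germ cell comparison. A gene withheld for evaluation is not reported here. The comparisons, tests, lists, marker sets, naming rule and most alternatives were chosen before the data were examined.

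The alternatives chosen then were pseudocounts of 10 and 0.1, no filter on low values, the mean over cells of log2(RPM + 1), the median over cells, quantile normalization, eBayes without trend, units of 1 cell, Leiden resolutions of 0.6 and 1.5, an estimated correlation in camera, and leaving out each unit in turn. Added after seeing the data were the quasi-likelihood test of edgeR 4.0.16 on recovered reads and fits with only the 2 classes compared. Also added then were fits without a CMK6 cell whose description and source name disagree, fits without 11 gonadal cells that held at least 3 gonadal somatic genes at 50 RPM, and all alternatives of the test with embryo PGC-like cells except the median over cells. The code beginning MS in each title was used as a candidate batch. Directions given within a title code come from cells that the fits hold as well, so they are no independent check. The tests were tried on simulated values, drawn as normal noise around the mean of each gene with its residual SD. In these, 200 genes were changed by known sizes. That is fewer than passed in most comparisons, so the shares recovered are a rough guide to the fits as reported. At a log2 change of 3, 60% of changed genes were recovered between gonadal germ cells and ESCs, 48% between PGCLCs and ESCs, 44% between gonadal germ cells and PGCLCs, 90% between EPI-like cells after and before implantation, and 42% between PGCLCs and embryo PGC-like cells. Single-cell units of E47 and E55 and PGC-like cells of E14, E17 and E20 were left out of the tests because they held fewer than 5 cells. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.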

Results

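To set PGCLCs beside the cells of the embryo they are meant to resemble, 605 single cells of cynomolgus monkey were grouped by embryonic day, cell line or culture medium. They comprised 540 cells of embryos, of which 384 came from after implantation (E13 to E20) and the others from before it (E06 to E09), 28 ESCs of 3 lines, 12 PGCLCs from 2 media and 25 gonadal germ cells of E36 to E55. Values are mean RPM, reads scaled to the mapped reads of a cell, with the SD over units for tested comparisons and over cells otherwise, and log2 changes carry their standard error. A unit is the mean of the cells of 1 line, medium or embryonic day. Adjusted p-values come from limma and measure only the spread between these units, because the labels name no separate cultures or animals. The cells of a group correlated with each other at a median r of between 0.693 in E13 and 0.872 in CMK9.

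Clusters of the 540 embryo cells were named by marker genes to find PGC-like and epiblast-like (EPI-like) cells. Of 15 clusters, 1 of 24 cells was PGC-like and 3 were EPI-like, with 75, 52 and 41 cells. PGC-like cells made up 6.2% of the cells of E13 (7 cells, 95% CI 2.5 to 12.3), 6.4% of E16 (11 cells, 3.3 to 11.2) and 7.1% of E17 (4 cells, 2.0 to 17.3). None of the 86 cells of E08 was PGC-like (upper bound 4.2%). EPI-like cells made up 36.7% of E07 (19.9 to 56.1), 27.9% of E08 (18.8 to 38.6), 37.5% of E09 (15.2 to 64.6), 25.7% of E13 (17.9 to 34.7), 64.1% of E14 (47.2 to 78.8), 24% of E16 (17.8 to 31.1) and 57.1% of E17 (43.2 to 70.3). The name of those of E17 depended on the resolution, since 32 cells of that day had it as reported and 1 at a resolution of 1.5. The intervals cover counting error only, and the shares depend on how cells were picked, which the labels do not give. SOX17, TFAP2C, PRDM1, NANOS3 and KIT named the PGC-like cluster, and POU5F1, NANOG, SOX2, GDF3 and DNMT3B helped to name the EPI-like clusters, so the levels of these genes are not independent evidence for those types.

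To describe the first 8 days of induction, PGCLCs of both media were set beside the 656BTAG ESCs they came from. SOX17, needed for primate germ cell specification, averaged 6.87 ± 6.52 RPM in 8 cells at day 0, 470.73 ± 169.15 in 6 cells in GK15 and 463 ± 209 in 6 cells in aRB27. PRDM1 averaged 3.63 ± 3.08, 448 ± 361 and 323.01 ± 130.62, and TFAP2C 17.7 ± 17.7, 459 ± 233 and 707 ± 182 in the same order. SOX2 went the other way, from 377.19 ± 225.44 at day 0 to 4.91 ± 5.14 in GK15 and 7.80 ± 7.44 in aRB27. NANOS3 averaged 0.48, 55.1 ± 80.1 and 44.3 ± 32.3, and KIT 12.7 ± 26.5, 265.74 ± 100.97 and 145.32 ± 134.70. POU5F1 (947.11 ± 211.53, 2278 ± 288 and 2751 ± 590) and NANOG (151.81 ± 86.84, 953 ± 355 and 934 ± 299) were higher at day 8. DDX4 was listed at 0 in both media, and DAZL averaged 0.81 in GK15 and 0.48 in aRB27. The cells were sorted on the BTAG reporter, so germ cell genes linked to that reporter would be high by selection. There was 1 culture per group, so no test was made.

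Beyond these genes, 1246 of 10078 genes differed at least 4-fold from day 0 in both media in the same direction, 647 higher and 599 lower. These are counts by size, not calls. A further 43 differed 4-fold in opposite directions, and with a pseudocount of 10 the count of 1246 was 339. With medians over cells the balance turned to 531 higher and 978 lower. The largest ratios upward belonged to HPGD (1.58 at day 0, 907 ± 599 in GK15 and 639 ± 316 in aRB27), TFCP2L1, TPH2, FMO5, SPON2, ABCG1, GREM1, ADCYAP1, PPP1R14C and T. T, the mesoderm gene brachyury, averaged 1.72 ± 1.56, 281 ± 298 and 310.85 ± 215.92. Downward they belonged to B2M, SFRP1, VTCN1, TAGLN, DRAXIN, SPP1, CDH6, CLU, CD24 and CUZD1. At day 0 SPP1 averaged 563 ± 1351 and CUZD1 72.9 ± 180.8, with SDs well above the mean, so few cells may carry these values. B2M, the light chain of MHC class I, averaged 1328 ± 457 at day 0, 0.26 ± 0.42 in GK15 and 0.39 ± 0.48 in aRB27. The early germ cell list had a median log2 ratio of 3.38 in GK15 and 2.97 in aRB27, above all of 10000 random lists in both. The post-implantation pluripotency list had medians of -2.41 and -1.46, below all of them. The mesoderm list (2.13 and 2.84, percentiles 99.25 and 99.81) and the BMP response list (1.24 and 2.22, percentiles 99.23 and 100) were higher. Genes entered a list at a mean of 10 RPM in day 0, GK15 or aRB27. All 8 measured mesoderm genes were below that at day 0, so they entered through day 8 and a higher median was favoured. The random lists were not matched on the day 0 level. EVX1 was higher only in GK15, and EOMES and CDX1 only in aRB27. Other lists with higher medians hold such genes too, such as SOX17, PRDM1 and GATA3. Lists of other lineages had higher medians, which rested on few genes, namely amnion (1.99 and 3.45, 7 genes), trophectoderm (2.07 and 2.46, 7 genes), endoderm (2.38 and 2.11, 4 genes) and extraembryonic mesenchyme (1.64 and 1.65, 7 genes, percentiles 98.92 and 98.78). Of the 7 amnion genes 2 were at least 4-fold lower in each medium, VTCN1 among them. The first 3 share GATA3, TFAP2A and SOX17 with the lists above. The proliferation list had lower medians (-1.06 and -0.64, percentiles 0 and 0.36), but 2 of its 18 genes were at least 4-fold lower in GK15 and none in aRB27. In the test of PGCLCs against all ESC lines, the amnion (adjusted p = 0.277 with the preset correlation), endoderm (0.121), extraembryonic mesenchyme (0.149) and proliferation lists (0.149, with none of 18 genes passing) did not pass.

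**Figure D1:**
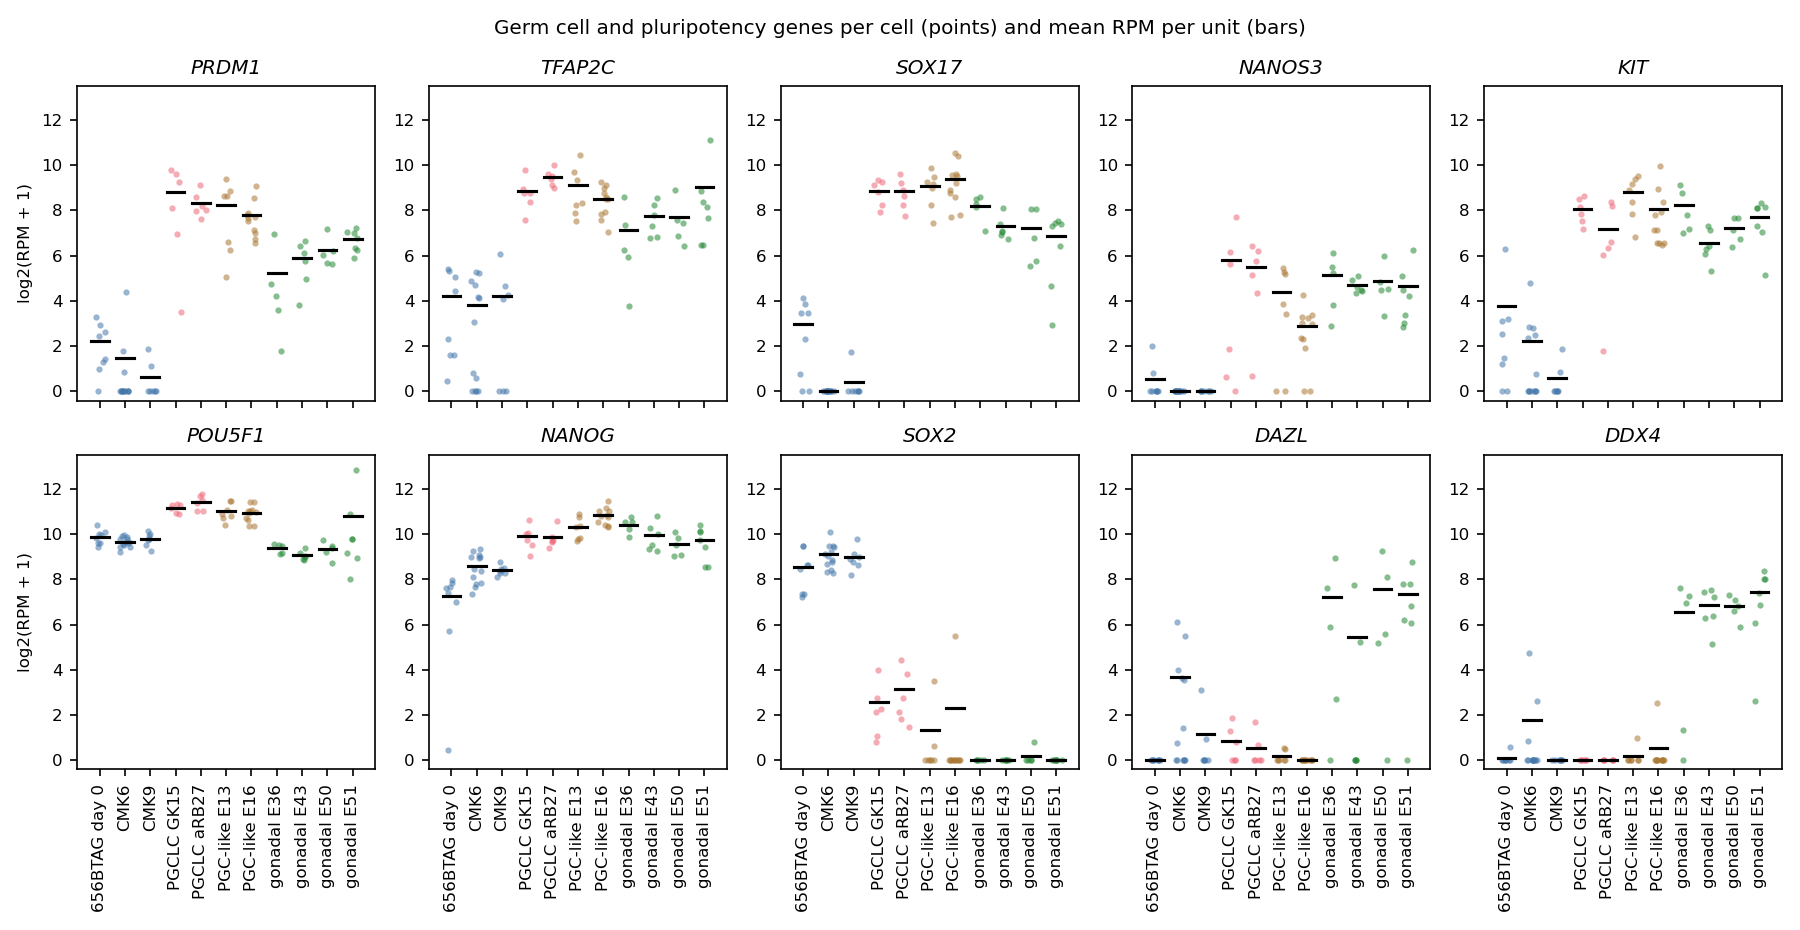
RPM of 10 germ cell and pluripotency genes, with a point for each cell and a bar for the mean of each of 11 units, as log2(RPM + 1). DDX4 averaged 123.14 RPM in gonadal germ cells and was listed at 0 in both PGCLC media.

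To describe how PGCLCs from the 2 basal media differed, those from GK15 and aRB27 were set against each other. There was 1 culture of 6 cells per medium, so no test was made. An effect of the medium cannot be told apart from a difference between cultures. DLC1 averaged 76.4 ± 58.1 RPM in 6 cells in GK15 and was listed at 0 in 6 cells in aRB27. ADM, a gene induced by hypoxia, averaged 347 ± 298 in GK15 and 28.1 ± 60.1 in aRB27. KCTD20 averaged 0.54 ± 0.76 in GK15 and 68.5 ± 39.6 in aRB27, and CYP4X1 was listed at 0 in GK15 and averaged 57.03 ± 58.09 in aRB27. Other genes higher in GK15 were SPR, ANKRD63, IL20RA, ZNF395, OSBPL8, SNX4 and GMPR, and FAM200B, MDFIC, GALNT16, HARS2, RIOK1, MSL2, RSRP1 and APEX2 were higher in aRB27. The glycolysis list was higher in GK15, with a median log2 ratio of 0.73 (percentile 99.98). Of its 18 genes 3 were at least 4-fold higher there and 1 at least 4-fold lower. The early germ cell list was level between media (0.03, percentile 55.8). The extraembryonic mesenchyme list had a higher median in GK15 (0.88, percentile 98.26, 6 genes), but 1 of its genes was at least 4-fold higher there and 2 at least 4-fold lower. Log2 mean levels correlated between media across 9230 genes at r = 0.653 (95% CI 0.641 to 0.665) and rho = 0.706. Across the same genes r was 0.67 between day 0 and GK15 and 0.694 between day 0 and aRB27. Genes are not independent replicates, so the interval covers the spread over genes only. The order of the 3 correlations turned with medians over cells (0.785 between media, 0.726 and 0.735 with day 0) and with a pseudocount of 10 (0.8, 0.753 and 0.772), so which pair was closest depended on the processing.

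To test which genes separate PGCLCs from ESCs, 2 PGCLC units were compared with 3 ESC units. Both PGCLC units came from the same ESC line, so they hold no spread between lines, here and in each later comparison with PGCLCs. The other ESC lines were kept in a different medium. Line and ESC medium are therefore not separated from class here, and the comparison within the line, given above, had no test. SOX17 rose from 2.40 ± 3.87 RPM in ESCs to 467 ± 5.48 in PGCLCs (log2 change 7.74 ± 0.72, adjusted p = 1.48e-05). The SD of 5.48 is that of 2 unit means, and SOX17 varied far more over PGCLC cells, as given above. PRDM1, which represses the somatic program in germ cells, rose from 1.99 ± 1.55 to 385 ± 88.2 (7.13 ± 0.61, adjusted p = 8.81e-06), and TFAP2C from 16.2 ± 2.71 to 583 ± 175 (5.06 ± 0.47). SOX2 fell from 476 ± 88.4 to 6.36 ± 2.05 (-6.03 ± 0.71, adjusted p = 0.000104). NANOS3 (5.47 ± 0.73), KIT (5.43 ± 0.74), NANOG (1.79 ± 0.36, adjusted p = 0.00627) and POU5F1 (1.51 ± 0.39, adjusted p = 0.0211) rose too. NANOG and POU5F1 lost their calls in some alternatives, as given below. DAZL (adjusted p = 0.637) and DDX4 (adjusted p = 0.696) did not pass.

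In all, 1169 of 10557 genes passed between PGCLCs and ESCs, 525 higher and 644 lower in PGCLCs, with a median of all genes of -0.17 (-0.05 after quantile normalization) beside which these changes stand. In 1168 of them the units did not overlap, while chance gives this in 20% of genes, called or not, with 2 and 3 units. Called genes are selected for separation, so such counts are no test. The genes with the largest rise were HPGD, SOX17, ADCYAP1, T, ABCG1, CXCR4, PRDM1, TPH2, TFCP2L1 and PLCXD3, and those with the largest fall B2M, SFRP1, SPP1, TAGLN, GPR176, CRABP2, VTCN1, USP44, SOX2 and PRKCB. B2M fell from 1024 ± 375 to 0.32 ± 0.09 (-9.52 ± 0.72, adjusted p = 4.61e-06). T rose from 0.84 ± 0.86 to 296.03 ± 20.95 (7.45 ± 0.71, adjusted p = 1.69e-05). In the early germ cell list 11 of 19 genes rose and none fell (12 and 0 adjusted over the list alone), among them CXCR4 and TFCP2L1. In the post-implantation pluripotency list 8 of 20 fell and 1 rose (11 and 1 adjusted over the list alone), with DNMT3B at -4.83 ± 0.48 and SFRP1 at -8.90 ± 1.26. Both lists passed camera with an estimated correlation (adjusted p = 0.0157 and 0.0226). No gene of the 14 in the late germ cell list or the 9 in the meiosis list passed. The mesoderm list had 2 of 8 up (3 adjusted over the list alone), T and HAND1, and lost its call (adjusted p = 0.0881 with an estimated correlation). In the BMP response list MSX2, GATA3 and TFAP2A rose (3 of 10, 4 adjusted over the list alone, adjusted p = 0.562 with an estimated correlation). HAND1, GATA3 and TFAP2A also belong to the trophectoderm and amnion lists, of which the first had 3 of 6 up (4 adjusted over the list alone, adjusted p = 0.268 with an estimated correlation), and GATA4, an endoderm and gonadal somatic gene, rose with them (5.09 ± 0.65). All PGCLCs and 656BTAG ESCs carry title code MS168 and no CMK6 or CMK9 cell does, so no check of the direction apart from the fit was possible. The count was 473 without GK15, 763 without aRB27, 636 without CMK6 and 587 without CMK9, 710 without a filter and 485 with units of 1 cell. With edgeR, chosen after seeing the data, it was 578. The share higher in PGCLCs was 44.9% of the calls as reported, 26.8% with means of log2 (381 higher and 1039 lower), 53.2% with quantile normalization, 55.3% without CMK6, 58.3% without CMK9 and 62.1% with edgeR, so neither direction was the more frequent one throughout.

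To test what separates germ cells in the gonad from ESCs, 4 gonadal units were compared with 3 ESC units. DDX4, an RNA helicase of later germ cells, rose from 0.83 ± 1.38 RPM to 123.14 ± 32.63 (6.30 ± 0.69, adjusted p = 3.44e-05), and DAZL, an RNA-binding protein of the same stage, from 4.3 ± 6.44 to 135.81 ± 64.94 (5.29 ± 0.84, adjusted p = 0.000632). SOX17 rose to 179 ± 80.4 (6.27 ± 0.60), PRDM1 to 68.81 ± 28.99 (4.58 ± 0.51), TFAP2C to 272 ± 172 (3.81 ± 0.39), NANOS3 to 27.8 ± 4.44 (4.65 ± 0.61) and KIT to 187.61 ± 87.71 (5.23 ± 0.62). SOX2 fell from 476 ± 88.4 to 0.04 ± 0.08 (-8.83 ± 0.59, adjusted p = 7.24e-07). NANOG rose from 292.85 ± 124.57 to 990 ± 267 (1.83 ± 0.30, adjusted p = 0.000871), while POU5F1 did not pass (878 ± 70.7 and 903 ± 576, -0.13 ± 0.32, adjusted p = 0.81). Gonadal cDNAs were assigned to germ cells by quantitative PCR, so germ cell genes linked to that choice would be high by selection. The same holds in each later comparison with gonadal germ cells.

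A total of 2196 of 10557 genes passed between gonadal germ cells and ESCs, 1128 higher and 1068 lower in gonadal germ cells. Units did not overlap in 2099 of these selected genes (by chance in 5.71% of all genes with 4 and 3 units). The largest rises were those of TCL1B (277 ± 65.6 in gonadal germ cells, 7.70 ± 0.48), GIP, DCAF4L2, COX8C, GLB1L3, DDX43, NR2F2, NLRP2, TFCP2L1 and DNMT3L. The largest falls were those of SPP1, SOX2, USP44, ZIC2, TAGLN, GJA1, SFRP2, SFRP1, RGS16 and VTCN1. In the late germ cell list 13 of 14 genes tested rose (13 adjusted over the list alone), among them PIWIL2 (5.11 ± 0.69) and MAEL (5.00 ± 0.77), with adjusted p = 0.0968 with an estimated correlation. Other genes of this list were too low to be tested. DDX4, MAEL, DMRT1 and PIWIL2 averaged 0.83, 0.82, 0.49 and 0.42 RPM in ESCs and passed the filter only through gonadal units. The filter thus favoured rises, and the count of 13 is in part set by it. The early germ cell list had 15 of 19 up and 1 down, PRDM14 (16 and 1 adjusted over the list alone), and kept its call with an estimated correlation (adjusted p = 0.00668). The post-implantation list had 15 of 20 down and 1 up (16 and 1 adjusted over the list alone) and kept it too (adjusted p = 0.00474), with ZIC2 at -7.47 ± 0.79 and DNMT3B at -5.99 ± 0.40. In the pre-implantation list 7 of 10 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.16 with an estimated correlation), with TFCP2L1 and DNMT3L among them. Of the DNA and histone modifiers, DNMT1 (-1.86 ± 0.36), UHRF1 (-2.83 ± 0.71) and DNMT3A (-2.60 ± 0.53) fell, in a list with 3 of 20 up and 5 down (5 and 6 adjusted over the list alone) that did not pass. In the glycolysis list 9 of 18 fell and none rose (9 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation), among them SLC2A1 and ENO1. Genes of gonadal somatic cells rose in the same libraries, with 6 of 9 up (6 adjusted over the list alone, adjusted p = 0.227 with an estimated correlation). They included NR2F2 (117.11 ± 78.59, 6.42 ± 0.85) and WT1 (70.7 ± 70.4, 4.64 ± 0.86), and the collagen gene COL3A1 rose with them (4.79 ± 0.99). NR2F2 and WT1 also passed the filter only through gonadal units. Within title code MS132, 97.4% of the genes had the same direction in 4 gonadal germ cells and 3 ESCs. The count was 1307 without CMK9, 1398 without CMK6, 1430 with units of 1 cell and 1376 with edgeR. An alternative chosen after seeing the data left out 11 gonadal cells with at least 3 gonadal somatic genes, GATA4 counted, at 50 RPM. The calls of DAZL (3.99, adjusted p = 0.123) and NR2F2 (2.97, adjusted p = 0.0629) were then lost and the balance turned to 642 higher and 1092 lower. This left 2 cells in E36, 2 in E43, 5 in E50 and 4 in E51, so any effect of somatic RNA was not separated from that of small units. Cell 1 of E51, which held 440.2 RPM of DAZL, was left out only because GATA4 was counted. With means of log2 the balance was 1014 higher and 1432 lower.

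**Figure D2:**
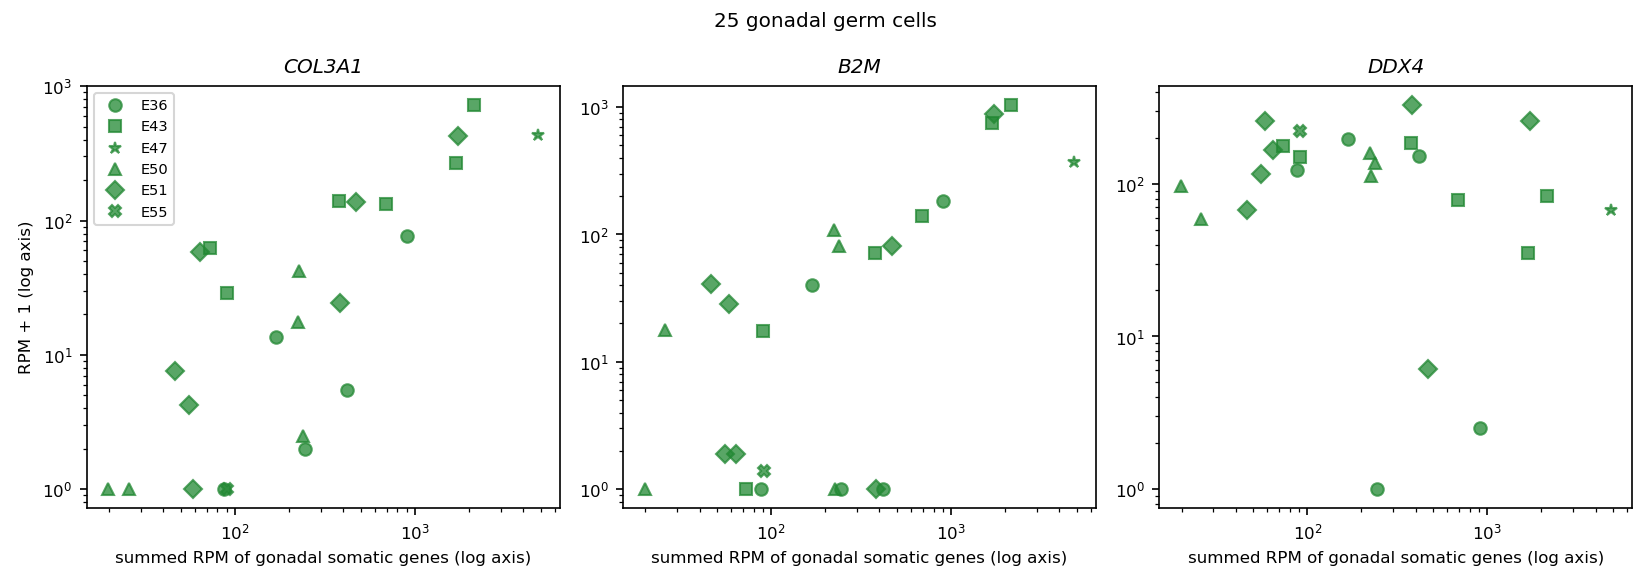
COL3A1, B2M and DDX4 in 25 gonadal germ cells against the summed RPM of gonadal somatic genes, with markers by embryonic day. Of the 25 cells, 11 held at least 3 of these genes at 50 RPM.

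Gonadal germ cells were then compared with PGCLCs, as 4 against 2 units, to find what day 8 cells lacked or held in excess. DDX4 was listed at 0 in PGCLCs and rose to 123.14 ± 32.63 RPM in gonadal germ cells (adjusted p = 0.00021), and DAZL rose from 0.64 ± 0.24 to 135.81 ± 64.94 (6.19 ± 0.96, adjusted p = 0.00164). UCP2, a mitochondrial carrier, fell from 1084 ± 11.3 to 0.26 ± 0.43 (-9.80 ± 0.76, adjusted p = 1.75e-05). The SD of 11.3 is that of 2 unit means. Over cells UCP2 was very uneven, at 1092 ± 1091 in GK15 and 1076 ± 1535 in aRB27. PRDM1 (-2.55 ± 0.58, adjusted p = 0.0121), POU5F1 (-1.65 ± 0.37, adjusted p = 0.0111) and SOX2 (-2.80 ± 0.67, adjusted p = 0.0161) were lower in gonadal germ cells. SOX17 (-1.47, adjusted p = 0.167), TFAP2C (-1.25, adjusted p = 0.0804), NANOS3, KIT and NANOG did not pass.

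Between gonadal germ cells and PGCLCs 1309 of 10557 genes passed, 786 higher and 523 lower in gonadal germ cells, with a median of all genes of 0.14 (0.02 after quantile normalization) beside which these changes stand. Units did not overlap in 1304 of these selected genes (by chance in 13.33% of all genes). The largest rises were those of NLRP7, DCAF4L2, COX8C, NLRP2, DDX4, RPL39L, RBM46, KRBOX1, MSL3B and RBM44, and the largest falls those of UCP2, COL2A1, NMU, TPH2, CNIH3, GJA1, EPAS1, SPON2, DUSP4 and MYH2. The late germ cell list had 9 of 14 up and none down (12 adjusted over the list alone, adjusted p = 0.132 with an estimated correlation), among them DMRT1 (5.93 ± 0.81), MAEL and PIWIL2, the last 2 listed at 0 in PGCLCs. DMRT1, MAEL and PIWIL2 passed the filter only through gonadal units, so it favoured a rise here too. The meiosis list had 2 of 9 up, SYCP3 and TEX11 (5 adjusted over the list alone, adjusted p = 0.367 with an estimated correlation). In the mesoderm list 4 of 8 fell (4 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation), with T at -2.41 ± 0.68. In the BMP response list ID1, ID3 and GATA3 fell (3 of 10, and 4 down and 1 up adjusted over the list alone, adjusted p = 0.405 with an estimated correlation). The glycolysis list had 8 of 18 down (10 adjusted over the list alone, adjusted p = 0.298 with an estimated correlation) and the cholesterol synthesis list 4 of 15 down and 1 up (8 and 2 adjusted over the list alone, adjusted p = 0.367 with an estimated correlation). The somatic genes WT1 (listed at 0 in PGCLCs), NR2F2 and LHX9 rose along with the germ cell genes. No title code held both kinds of cell, so batch and group cannot be told apart here. The count was 382 without GK15, 828 without aRB27, 585 without a filter, 580 with units of 1 cell and 580 with edgeR. Without the gonadal cells with at least 3 gonadal somatic genes at 50 RPM, which leaves units of 2 to 5 cells, it was 645. The balance then turned, with 42.8% of the calls higher in gonadal germ cells against 60% as reported. The calls of DAZL (4.88, adjusted p = 0.144), SOX2 (-2.80, adjusted p = 0.0514) and POU5F1 (-1.55, adjusted p = 0.0881) were lost, though the changes of SOX2 and POU5F1 kept about the same size.

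To place PGCLCs beside germ cells of the early embryo, they were compared with PGC-like cells of E13 (7 cells) and E16 (11 cells), a test the plan allowed if 2 days had 5 cells each. None of the 10 germ cell and pluripotency genes passed. SOX17, TFAP2C, PRDM1, NANOS3 and KIT helped to name the PGC-like cluster, and PGCLCs were sorted on the BTAG reporter. High levels of such genes on either side may therefore come from selection. With 2 units on each side, genes that did not pass are not shown to be alike. SOX17 averaged 467 ± 5.48 RPM in PGCLCs and 611 ± 91.4 in embryo PGC-like cells, TFAP2C 583 ± 175 and 462.96 ± 137.74, PRDM1 385 ± 88.2 and 263 ± 60.8, KIT 205.53 ± 85.15 and 357.01 ± 127.48, and NANOS3 49.7 ± 7.66 and 13.2 ± 9.55 (adjusted p = 0.22). POU5F1 (2514 ± 335 and 2003 ± 65.9), NANOG (944 ± 13.7 and 1537 ± 394), SOX2 (6.36 ± 2.05 and 2.77 ± 1.71), DAZL and DDX4 did not pass either. DMRT1, a germ cell transcription factor, was lower in PGCLCs (0.06 ± 0.09 against 86.2 ± 22.2, -6.34 ± 0.87, adjusted p = 0.00149), and PIWIL2 was listed at 0 in PGCLCs and averaged 63.3 ± 30.7 in embryo PGC-like cells (adjusted p = 0.00273). UCP2 was higher in PGCLCs (1084 ± 11.3 against 54.8 ± 33.4, 4.42 ± 0.85, adjusted p = 0.0138), with the wide spread over PGCLC cells given above.

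Of 10881 genes 261 passed between PGCLCs and embryo PGC-like cells, 73 higher and the others lower in PGCLCs, none with overlapping units. The median of all genes was -0.15 (0 after quantile normalization), beside which these changes stand. The largest differences upward were those of PLCXD3, PCDHB3, TNFRSF10D, FGFBP3, ADCYAP1, COL2A1, CNIH3, SOSTDC1, UCP2 and C1H1orf54, and downward those of NLRP2, NLRP7, DPPA5, DMRT1, DCAF4L2, RPL39L, GSTM3, KHDC3L, GLB1L3 and PIWIL2. The late germ cell list had 5 of 16 lower and none higher (9 lower adjusted over the list alone, adjusted p = 0.377 with an estimated correlation), and the pre-implantation list 5 of 12 lower (5 adjusted over the list alone, adjusted p = 0.377 with an estimated correlation), DPPA5 and DPPA3 among them. DMRT1 and PIWIL2 passed the filter only through embryo and gonadal units, which favoured lower values in PGCLCs. In the glycolysis list 1 of 18 genes passed, HK1 (3 adjusted over the list alone), and the list did not pass camera with an estimated correlation (adjusted p = 0.377). PECAM1, which is also an endothelial gene, was lower in PGCLCs (4.86 ± 3.35 against 238.82 ± 134.16, adjusted p = 0.00851), as was CGA of the trophectoderm list. No title code was shared, so batch and group cannot be told apart. As a percent of the 261 genes the count was 35.25% with medians over cells. In alternatives chosen after seeing the data it was 10.73% (28 genes) without E13, 17.62% without GK15, 45.21% without E16, 54.41% without a filter, 61.3% with means of log2, 18.39% with units of 1 cell, 167.82% with a unit of 4 cells of E17, 3.07% (8 genes) with only these 2 classes in the fit and 32.57% with edgeR. The share higher in PGCLCs was 28% of the calls as reported, but 57.6% with medians (53 higher and 39 lower), 56.9% with means of log2, 50.8% without E16 and 2.2% without GK15, so the balance of directions depended on the processing.

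Gonadal germ cells were compared with the embryo PGC-like cells to find changes between the early embryo and the gonad. DAZL rose from 0.06 ± 0.09 RPM to 135.81 ± 64.94 (6.81 ± 0.99, adjusted p = 0.00328) and DDX4 from 0.29 ± 0.21 to 123.14 ± 32.63 (6.57 ± 0.82, adjusted p = 0.00124). T fell from 597.47 ± 116.23 to 67.04 ± 54.52 (-3.41 ± 0.59, adjusted p = 0.014). PRDM1 (-2.001, adjusted p = 0.0991), POU5F1 (-1.32, adjusted p = 0.102), SOX17, TFAP2C, NANOS3, KIT, NANOG and SOX2 did not pass. Only 87 of 10881 genes passed, 34 higher and 53 lower in gonadal germ cells, and units overlapped in none of these selected genes (by chance there is no overlap in 13.33% of all genes). The largest rises besides were those of NR2F2, OLFM4, WT1, CRIP1, KCTD12, ZNF521, ACTG2 and SMIM13, of which NR2F2 and WT1 are gonadal somatic genes, and the largest falls those of NMU, WFDC2, ADAM19, EPAS1, KRT19, UCP2, ENPP2, TPH2, GJA1 and HACD1. The mesoderm list had 2 of 8 down, T and WNT3 (6 adjusted over the list alone), and kept its call with an estimated correlation (adjusted p = 0.0115). The late germ cell list had 3 of 16 up, DAZL, DDX4 and RNF17 (5 adjusted over the list alone, adjusted p = 0.259 with an estimated correlation). DDX4, near 0 in every other class of the fit, passed the filter only through gonadal units, which favoured its rise. The same direction was found in 98.9% of the 87 genes within title code MS117 (19 gonadal and 9 embryo cells) and in 96.6% within MS132 (4 and 4 cells). In alternatives chosen after seeing the data no gene kept its call with limma without E13, which leaves only E16 as an embryo unit. The limma count was 47 without E43, 54 without E50 and 53 without E51. Also chosen then, it was 34 with a pseudocount of 0.1, 39 with units of 1 cell, 38 with 2 classes in the fit and 19 with edgeR, where DDX4 (adjusted p = 0.0719) and DAZL (adjusted p = 0.120) did not pass. It rose to 168.97% of the 87 genes with a pseudocount of 10 and to 178.16% with means of log2. The share higher in gonadal germ cells was 39.1% of the calls as reported, 70.7% with medians over cells (65 higher and 27 lower), 69% with means of log2, 71.9% without E16 and 10.5% with edgeR, so the balance of directions depended on the processing. Without the gonadal cells with at least 3 gonadal somatic genes at 50 RPM, with units of 2 to 5 cells left, 16.4% were higher. DAZL (5.50, adjusted p = 0.202), NR2F2 (2.93, adjusted p = 0.276), KCTD12 (1.23, adjusted p = 0.775), ZNF521 (3.28, adjusted p = 0.160), OLFM4 (4.24, adjusted p = 0.141) and CRIP1 (5.10, adjusted p = 0.0712) then lost their calls.

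Against both PGCLCs and gonadal germ cells, embryo PGC-like cells differed in 11 genes, 7 higher, 2 lower and 2 in opposite directions. Both comparisons rest on the same 2 embryo units, so a value of 1 unit enters both, and no number by chance was worked out. Without E13, left out after the data were seen, none of the 11 kept its call against gonadal germ cells. WFDC2 was higher in embryo PGC-like cells (203.11 ± 189.20 RPM, against 7.16 ± 4.04 in PGCLCs and 1.29 ± 2.01 in gonadal germ cells, adjusted p = 0.0400 and 0.00305). The 2 embryo units were uneven in other genes too, with FN1 at 476 ± 447 RPM and COL3A1, a collagen gene, at 0.53 and 280.17 RPM. FSTL1 was lower in embryo PGC-like cells (53.6 ± 1.22 against 256.71 ± 76 and 197 ± 62.7, adjusted p = 0.0231 and 0.0491). By size alone, 83 genes were at least 4-fold lower than both and a larger number at least 4-fold higher, led upward by WFDC2, GDF3, SLIT3 and SPP1 and downward by PLCXD3 and CRHBP. UCP2 was the reverse of a shared gene, at 54.8 ± 33.4 in the embryo, 1084 ± 11.3 in PGCLCs and 0.26 ± 0.43 in the gonad. These SDs are over units, and PGCLC cells varied far more.

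To ask whether induction in culture moved the same genes as germ cell development in the gonad, log2 ratios of PGCLCs over 656BTAG ESCs were set against those of gonadal germ cells over CMK6 and CMK9 ESCs, with no library shared. TFCP2L1, SOX17 and KIT were higher and SOX2 and DNMT3B lower in both. Across 10718 genes the ratios correlated at r = 0.409 and rho = 0.363. The r was 0.35 to 0.371 with single gonadal days, 0.353 with GK15 alone and 0.376 with aRB27 alone. Genes are not independent replicates, so no p-value is given. At 4-fold or more 360 genes were higher in both (105.7 if the 2 lists were independent) and 280 lower in both (67.5). Another 28 were higher in PGCLCs and lower in gonadal germ cells (86.2 if independent) and 39 the reverse (82.7). The r was 0.54 among 5272 genes of at least 50 RPM and 0.312 with the gonadal germ cells and CMK6 ESCs limited to title code MS132, the PGCLC ratios unchanged.

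**Figure D3:**
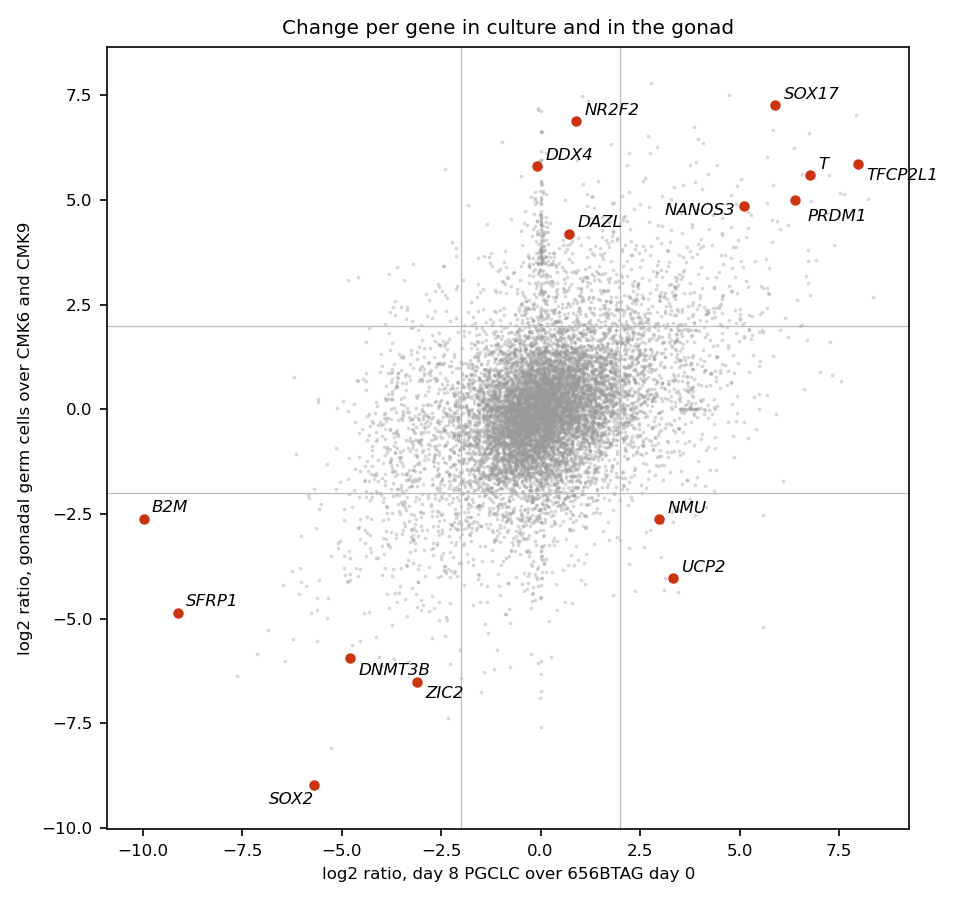
Log2 ratios of PGCLCs over 656BTAG ESCs against gonadal germ cells over CMK6 and CMK9 ESCs for 10718 genes, with named genes in red and lines at a log2 ratio of 2 in each direction. The correlation across genes was r = 0.409.

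To follow the epiblast across implantation, EPI-like cells of 4 days after implantation (E13, E14, E16 and E17) were compared with those of 3 days before it (E07, E08 and E09). All 41 cells before implantation formed 1 cluster. Those after it formed 2 others, of 52 cells of E13 and E14 and of 75 cells, 73 of them of E16 and E17, so type names, clusters and days changed together. NANOG fell from 2104 ± 261 RPM to 566 ± 210 (-1.96 ± 0.33, adjusted p = 0.000715), while POU5F1 rose from 620 ± 85.4 to 1020.89 ± 126.39 (0.72 ± 0.16, adjusted p = 0.00509) and SOX2 did not pass (361.67 ± 19.01 and 393.45 ± 112.19). DPPA3, a maternal factor, fell from 455 ± 98.6 to 25.4 ± 26.3 (-4.97 ± 0.81, adjusted p = 0.000646), KLF4 from 327.76 ± 154.18 to 20.62 ± 20.28 (-4.62 ± 0.90) and TFAP2C from 184 ± 9.63 to 6.0 ± 3.1 (-4.84 ± 0.36). Among DNA methyltransferases, DNMT3L fell from 437 ± 61.9 to 31.2 ± 36.8 (-5.28 ± 1.06), and DNMT3B (1417 ± 279 to 3103 ± 894, 1.10 ± 0.27) and DNMT1 (32.5 ± 10.2 to 156.41 ± 56.14, 2.21 ± 0.29) rose.

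A total of 2616 of 9718 genes passed across implantation, 1336 higher and 1280 lower after it, and in 2532 of these selected genes units did not overlap (by chance in 5.71% of all genes). The largest rises were those of VCAN, SFRP1, LDB2, VAT1L, CAV1, CCND2, FERMT1, FHL2, CD24 and HMGA2. The largest falls were those of S100P, FAM240A, KRT33A, DPRX, NLRP7, CD53, ANPEP, KHDC1L, DPP4 and BRDT, with S100P at 1075 ± 265 before and 2.59 ± 3.12 after (-8.67 ± 0.60). The pre-implantation pluripotency list had 12 of 15 down and 1 up, ZFP42 (13 and 1 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation). The post-implantation list had 15 of 20 up and none down (16 adjusted over the list alone, adjusted p = 0.0681 with an estimated correlation), with SFRP2 (4.73 ± 0.47) and FGF2 (3.02 ± 0.34) among them. DPPA5 fell (-2.33 ± 0.81, adjusted p = 0.048), with unit means of 1731 RPM in E13, 1573 in E14, 176 in E16 and 96.3 in E17, which divide as the 2 clusters do. The glycolysis list had 9 of 18 up and 1 down (11 and 1 adjusted over the list alone, adjusted p = 0.132 with an estimated correlation), with PKM and TPI1 among them, and the oxidative phosphorylation list 8 of 21 down (8 adjusted over the list alone, adjusted p = 0.296 with an estimated correlation). In the cholesterol synthesis list 6 of 15 rose (6 adjusted over the list alone, adjusted p = 0.543 with an estimated correlation), DHCR7 among them. The mesenchymal genes VIM (4.33 ± 0.76) and COL1A1 (3.01 ± 0.42) rose in the same comparison. Within title code MS126 (26 cells after and 15 before) 99.8% of the genes had the same direction. With means of log2 the balance turned to 1021 higher and 1964 lower. The total count was moved by more than 1.5 times by no alternative or left-out unit.

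**Figure D4:**
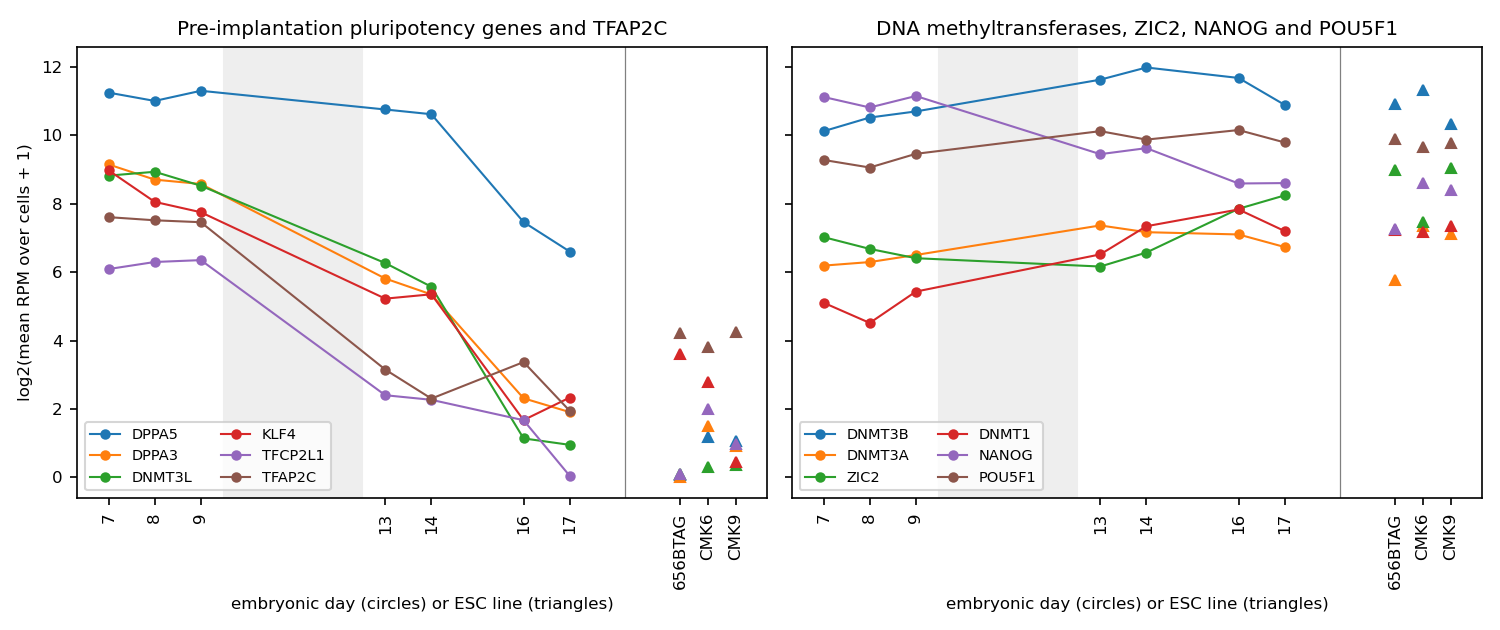
RPM of 12 genes in EPI-like cells by embryonic day (circles) and in 3 ESC lines (triangles), with a grey band over days without cells. DPPA5 averaged 1731 RPM in E13 and 96.3 RPM in E17.

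To find which epiblast the ESCs resembled, 3 ESC lines were compared with the EPI-like cells of both periods. Against the cells after implantation 400 of 9718 genes passed, 56.2% of them higher and 175 lower in ESCs, and in 390 units did not overlap. DPPA5 was lower in ESCs (0.80 ± 0.66 RPM against 894 ± 878, -8.09 ± 0.81, adjusted p = 9.86e-05), as were KHDC3L, KRBOX1, TRIM60, NLRP2, DMRTB1, OOEP, TRIML2, GDF3 and PTCH1. TAGLN, a gene of contractile cells, was higher in ESCs (759 ± 579 against 13.49 ± 7.49, 5.63 ± 0.59, adjusted p = 0.000127), as were TRIB3, ARC, ACTA1, ACTG2, SLC7A11, VIM, PTRF, MYL9 and SPP1. POU5F1, NANOG, SOX2 and DNMT3B did not pass. The pre-implantation list had 4 of 15 lower, DPPA5, ZFP42, FGF4 and SOX15 (7 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation). The stress list had 4 of 12 higher (5 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation), with TRIB3 and DDIT3 among them, and the meiosis list 3 of 4 lower (3 adjusted over the list alone, adjusted p = 0.0582 with an estimated correlation), with REC8 and SYCP3. Within title codes MS130 and MS132 the direction was the same in 95.2% and 96.5% of the genes. As a percent of the 400 genes the count was 36.5% without CMK9, 169.25% without 656BTAG, 51% without E13, 50.25% without E14 and 61.25% without E16, 46.5% without a filter and 157.25% with means of log2. In alternatives chosen after seeing the data it was 52.75% with 2 classes in the fit and 53.5% with edgeR. The share higher in ESCs was 82.2% with means of log2, 45.3% without CMK6, 43.8% without CMK9 (64 higher and 82 lower), 48.9% without a filter and 47.2% with edgeR, so neither direction was the more frequent one throughout.

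Against EPI-like cells before implantation ESCs differed in 2827 of 9718 genes, 1556 higher and 1271 lower in ESCs, and in 2715 units did not overlap. KHDC3L was lower in ESCs (2.76 ± 2.70 RPM against 4740 ± 399, -10.66 ± 1.07, adjusted p = 1.28e-05), as were DPPA5, NLRP7, OOEP, NLRP2, S100P, DNMT3L, TRIM60, DPRX and DPPA3. NANOG was lower in ESCs as well (292.85 ± 124.57 against 2104 ± 261, -2.94 ± 0.35, adjusted p = 4.6e-05), and POU5F1 higher (878 ± 70.7 against 620 ± 85.4, 0.51 ± 0.17, adjusted p = 0.041). VIM was higher in ESCs (637 ± 435 against 1.21 ± 1.17, 7.91 ± 0.81, adjusted p = 1.49e-05), as were TAGLN, CAV1, GPR176, SFRP1, FHL2, HMGA2, VCAN, CCND2 and FKBP10. The pre-implantation list had 14 of 15 lower and the post-implantation list 16 of 20 higher (14 and 16 adjusted over the list alone), and both kept their calls with an estimated correlation (adjusted p = 0.0474 each). The oxidative phosphorylation list had 10 of 21 lower (11 lower and 1 higher adjusted over the list alone, adjusted p = 0.344 with an estimated correlation), COX6C among them. No title code held enough cells of both kinds for a check of direction within it, so batch and group cannot be told apart. No alternative moved the count by more than 1.5 times.

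The remaining lists are given for gonadal germ cells against ESCs. The meiosis list had 4 of 9 up, SYCP3 and TEX11 among them (7 adjusted over the list alone, adjusted p = 0.227 with an estimated correlation). The oxidative phosphorylation list had 4 of 21 down (5 adjusted over the list alone, adjusted p = 0.448 with an estimated correlation). In the cholesterol synthesis list 2 of 15 rose and 4 fell (the same adjusted over the list alone), in the mesoderm list T and EVX1 rose of 8 (2 up and 3 down adjusted over the list alone), and in the BMP response list GATA3 rose and ID3 fell of 10 (the same adjusted over the list alone), and none of these 3 lists passed. The core pluripotency list had 5 of 11 genes down, SOX2 and LIN28A among them, and 1 up, NANOG (the same adjusted over the list alone, adjusted p = 0.227 with an estimated correlation). The proliferation list had 4 of 18 down, RRM2 and TYMS among them (6 adjusted over the list alone, adjusted p = 0.332 with an estimated correlation). In the endoderm list SOX17, GATA4, GATA6 and COL4A1 rose and AFP and APOE fell (the same adjusted over the list alone, adjusted p = 0.16 with an estimated correlation). In the trophectoderm list DAB2 and GATA3 rose of 6 (3 adjusted over the list alone, adjusted p = 0.357 with an estimated correlation). In the endothelium and blood list PECAM1 and KDR rose of 4 (2 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation). In the extraembryonic mesenchyme list DCN and COL3A1 rose of 9 (3 adjusted over the list alone), and in the amnion list GATA3 rose and VTCN1 fell of 6 (2 and 1 adjusted over the list alone), and neither list passed. In the neural ectoderm list FOXD3 fell of 3 genes tested and in the stress list TRIB3, ASNS and ATF4 fell and DNAJB1 rose of 12, and neither list passed.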

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

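All tests in this part were chosen after the result was seen, except the test of the title code on the genes called between gonadal germ cells and ESCs. Gonadal germ cells and ESCs differed in 2196 genes, while most of their cells carry different title codes. Among all 35 splits of these 7 units into groups of 4 and 3, only the real one, 1 split, gave as many, and the next highest gave 72. Of 2074 genes called without the cells of title code MS132, 2063 were measured within that code and 96% of them kept their direction between its 4 gonadal germ cells and 3 ESCs, which argues against the title code as the source of the difference. The real split was also the only one, 1 of 35, for EPI-like cells after against before implantation (35 genes in the next highest, 2616 in the real one) and for ESCs against EPI-like cells after implantation (19 and 400). EPI-like cells were picked by clusters of the same values, and these clusters divide by period. The result across implantation was therefore favoured by that choice and is no evidence against chance. With 3 ESC units and 3 EPI-like units before implantation only 1 of 10 splits reached 2827 genes (0 in the others), and 10 splits are too few for a share under 0.05.

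Gonadal somatic genes, GATA4 among them, were present in the libraries of gonadal germ cells, 11 of 25 of which held at least 3 of them at 50 RPM. Across the 25 cells their sum correlated with the collagen genes COL1A2 and COL3A1, which are not on the list, at a mean rho of 0.74 (r = 0.692 of log2 values, rho = 0.673 without the 2 farthest cells, 0.812 in 21 cells of MS117, against a median of 0.08 and a 95th percentile of 0.38 in random gene pairs), and with B2M at a rho of 0.64 (r = 0.525, 0.544, 0.66, against 0.01 and 0.42), so RNA of somatic cells in these libraries is a candidate source of those genes and of B2M. The cells are not independent samples, since they come from 6 days. A part of the title code in this pattern stays open, as 1 of 4 cells of MS132 held at least 3 somatic genes, which is too few to decide. GATA4 stood apart, because 100% of the 4 cells with no other somatic gene at 10 RPM held it (median 30.1 RPM). It also averaged 60.1 ± 4.54 RPM in PGCLCs and 34.6 ± 17.4 RPM in embryo PGC-like cells. Of those 4 gonadal cells, cells 4 and 1 of E50 were near the limit (11.9 and 13.9 RPM). Another, cell 7 of E51 (46.3 RPM), was the shallowest library. Somatic RNA therefore need not be the only source of GATA4, but these cells are too few to decide. Cell 2 of E36 and cell 1 of E51 reached 3 somatic genes only with GATA4 counted (87.1 and 90.4 RPM). Whether any somatic RNA came from whole neighbouring cells or from free RNA, and whether germ cells express B2M or NR2F2 at a low level, stays open.

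B2M was near 0 in all 12 PGCLCs, with a highest value of 1.2 RPM. A loss of its reads in libraries of title code MS168 is argued against by the 8 ESCs of the same line and code, the lowest of which held 678.5 RPM (the highest 2040.9). Sequencing depth is argued against as well, since a PGCLC cell at the day 0 level would hold at least 1373 reads of B2M and none held more than 2, with the shallowest at 1033373 reads. A lower level of B2M in PGCLCs therefore remains as a hypothesis, found and tested on the same cells. The sort on BTAG, the culture itself and a change in the 3-prime end of the transcript were not tested.

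In 13 of 87 groups 1 value lay far from the others by Dixon's test, where chance gives about 1 in 20, or 4.3, if values are normal. The test was run on raw values, which are skewed in single cells, and all 13 lay above the others. The excess over 4.3 is therefore not shown to be beyond chance. Among the gonadal units POU5F1 was 1762.4 RPM in E51, far from the other 3 (533.8 to 663.2). That unit holds cell 7 with 7379.95 RPM of POU5F1 (others 257.2 to 1909.1) and 2230.5 of TFAP2C (86.95 to 457.99), the shallowest library at 151085 reads. Cell 6 of E51 held 75.1 RPM of NANOS3 (6.3 to 33.1). In E50, cell 5 was far from the others in PRDM1 (144.2, others 48.1 to 72.6) and TFAP2C (485.2, others 85.5 to 190.4). PRDM1 was 124.96 in cell 3 of E36 (2.44 to 26.13) and DAZL 216.8 in cell 6 of E43 (0 to 35.95). Among PGCLCs, NANOG was 1518.2 in cell 2 of aRB27 (669.2 to 929.0) and NANOS3 206.8 in cell 6 of GK15 (0 to 71.3), and cell 6 of aRB27 had 2457103 reads (1597126 to 1762003). Among ESCs, KIT was 77.9 in cell 1 of 656BTAG (0 to 8.2) and TFAP2C 66.99 in cell 4 of CMK9 (0 to 24.4).

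Some genes passed against ESCs in opposite directions in PGCLCs and gonadal germ cells, and the difference itself passed between gonadal germ cells and PGCLCs. There were 11 of them, 5 higher in PGCLCs and 6 higher in gonadal germ cells, and the 7 given here had a symbol, at least 50 RPM and a change of at least 2-fold in PGCLCs or gonadal germ cells, the last limit set after the values were seen. UCP2 rose in PGCLCs (4.92) and fell in gonadal germ cells (-4.89), a difference of -9.80. NMU rose and fell likewise (3.92 and -3.11, difference -7.03), as did ATP6V1C2 (1.31 and -1.22, difference -2.53) and ZNF706 (1.35 and -0.75, difference -2.10). RPL39L fell in PGCLCs and rose in gonadal germ cells (-4.09 and 2.67, difference 6.76), as did CHN1 (-2.23 and 1.59, difference 3.82) and NAE1 (-1.13 and 0.97, difference 2.10).

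Germ cell genes were also present in cells outside the tested comparisons, most of them above the highest ESC. The gonadal cell of E47 held 66.8 RPM of DDX4, 291.4 of DAZL and 148.6 of SOX17, and the gonadal cell of E55 held 219.7 of DDX4 and 275.1 of SOX17, while the highest ESC held 25.6, 67.8 and 16.4. DAZL in the cell of E55 was 30 RPM, below the highest ESC. The 4 PGC-like cells of E17 averaged 17.7 RPM of NANOS3 and 502.2 of SOX17, and the PGC-like cell of E20 held 55.2 and 548.8, while the highest ESC held 3.1 of NANOS3. Gonadal cells were assigned to germ cells by quantitative PCR, and SOX17 and NANOS3 helped to name the PGC-like cluster. High levels in these cells may therefore come from selection and are no independent evidence.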

How the results depend on the processing

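Some of the alternatives below were chosen after seeing the data. They were edgeR, fits with 2 classes, fits without the gonadal cells with at least 3 somatic genes, and the unit of E17. All alternatives for embryo PGC-like cells except medians over cells were chosen then as well. Among 3795 values of named genes under an alternative, 3447 kept their direction and side of the threshold, 307 lost their call, 19 gained one, 22 moved and 0 reversed. Genes that stayed on the same side of the threshold in every setting, those without a call included, numbered 26 of 29 between gonadal germ cells and ESCs and 22 of 27 between PGCLCs and ESCs, but 4 of 28 between gonadal germ cells and embryo PGC-like cells. POU5F1 between PGCLCs and ESCs lost its call in 7 settings and NANOG in 3. Pseudocounts, quantile normalization, eBayes without trend, both Leiden resolutions and the CMK6 cell with conflicting labels moved no count by more than 1.5 times outside the cases below. At a resolution of 1.5 the EPI-like cells of E17 fell from 32 to 1 and left the fit, and the count across implantation was 75.11%.

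Counts are given as a percent of the genes that passed in the comparison as reported (2196, 1169 and 1309 for gonadal germ cells against ESCs, PGCLCs against ESCs and gonadal germ cells against PGCLCs, 400 for ESCs against EPI-like cells after implantation, and 261 and 87 for PGCLCs and gonadal germ cells against embryo PGC-like cells). Without a filter, which roughly doubles the genes tested, the count was 60.74% for PGCLCs against ESCs, 44.69% for gonadal germ cells against PGCLCs, 46.5% for ESCs against EPI-like cells after implantation and 54.41% for PGCLCs against embryo PGC-like cells. With units of 1 cell it was 65.12% for gonadal germ cells against ESCs, 41.49% for PGCLCs against ESCs, 44.31% for gonadal germ cells against PGCLCs, and 18.39% and 44.83% against embryo PGC-like cells. With edgeR the 6 counts, in the order above, were 62.66%, 49.44%, 44.31%, 53.5%, 32.57% and 21.84%. With means of log2 the last 3 were 157.25%, 61.3% and 178.16%, and with 2 classes 52.75%, 3.07% and 43.68%. Against embryo PGC-like cells, medians gave 35.25% and the unit of E17 gave 167.82% for PGCLCs, and pseudocounts of 10 and 0.1 gave 168.97% and 39.08% for gonadal germ cells. Without the gonadal cells with at least 3 somatic genes, in units of 2 to 5 cells, the count was 49.27% for gonadal germ cells against PGCLCs. A pseudocount of 10 gave 339 genes at day 8 (1246). The r between media was 0.785 with medians, 0.8 with a pseudocount of 10 and 0.672 with quantile normalization (0.653). The r between PGCLC and gonadal changes was 0.54 at 50 RPM, 0.43 with a pseudocount of 10 and 0.312 with the gonadal and CMK6 cells limited to MS132 (0.409). Of the list tests 67 passed with the preset and 7 with an estimated correlation. With means of log2 the more frequent direction turned between gonadal germ cells and ESCs (41.5% up against 51.4%), across implantation (34.2% against 51.1%) and in both comparisons with embryo PGC-like cells (56.9% against 28% and 69% against 39.1%). Apart from the filter, the cause was not tested.

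With each unit left out in turn the counts ran from 59.52% to 98.04% for gonadal germ cells and from 40.46% to 102.65% for PGCLCs against ESCs, 29.18% to 115.43% for gonadal germ cells against PGCLCs, 67.7% to 89.68% across implantation, 36.5% to 169.25% and 74.14% to 104.21% for ESCs against EPI-like cells after and before it, and 10.73% to 97.32% for PGCLCs and 0% to 120.69% for gonadal germ cells against embryo PGC-like cells. The lowest value of the last range came without E13, with limma, which leaves only E16 as an embryo unit. A class left with 1 unit was assumed to vary like the others. No cell was shallow enough to be left out under the rule on genes per cell (0 cells removed), so that alternative was void. No paired analysis was made, because the replicate numbers that groups share mark no common animal, culture or day. Some groups share title codes, and a fit with the code as a block was left out. At a simulated log2 change of 2, limma recovered 22% of changed genes between PGCLCs and ESCs and 72% across implantation, so genes that did not pass are not shown to be unchanged.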

Other observations

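No test was made in this part. Shares of types outside the comparisons differed between embryonic days. Gastrulating-like cells, in a cluster led by MESP1, made up 17.5% of E16 (95% CI 12.2 to 24.1), 7 of 56 cells of E17 (5.2 to 24.1%) and 1.8% of E13 (0.2 to 6.2). Extraembryonic mesenchyme-like cells made up 31% of E13 (22.6 to 40.4) and 26.3% of E16 (19.9 to 33.6), but 1.8% of E17 (0 to 9.6) and none of 39 cells of E14 (upper bound 9.0%). Of the 45 such cells of E16, 36 were in a cluster whose score of 2.06 only just passed the limit of 2. Its leading genes, THBD and BNC1 among them, did not include DCN or COL3A1. The other 9 were in a cluster with a score of 5.76 that had DCN and COL3A1 among its leading genes. Hypoblast or yolk sac endoderm-like cells made up 41.9% of E08 (31.3 to 53) and trophectoderm-like cells 30.2% of E08 (20.8 to 41.1). A cluster of 53 cells (18 of E13, 13 of E14 and 22 of E16) had EVX1, MIXL1, T and WNT8A among its leading genes and took no name, because its best score of 2.33 was level with that for EPI (2.32). A cluster of 18 cells, mostly of E17, was led by CHRD, FOXA2, GSC and LHX1, and no type reached the limits for its name. All 24 cells of E06 and 8 of E07 formed a cluster without a name, with SPIC and DPRX among its leading genes.

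Some genes of interest outside the naming rule, singled out after their values were seen, differed between germ cell classes without a test between all of them. OTX2 averaged 22.6 ± 8.18 RPM in ESCs, 26.5 ± 7.28 in PGCLCs, 10.4 ± 4.73 in embryo PGC-like cells and 3.06 ± 2.43 in gonadal germ cells. TET1 averaged 109.20 ± 18.09, 48.77 ± 19.95, 93.82 ± 28.87 and 139.07 ± 25.32 in the same order, and KLF4 5.80 ± 5.37, 67.15 ± 1.49, 41.95 ± 14.50 and 124.50 ± 17.78. KLF17 averaged 18.7 ± 5.59 RPM in EPI-like cells before implantation and 3.60 ± 5.09 in embryo PGC-like cells, and was listed at 0 in PGCLCs and gonadal germ cells.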
